A study of Homo sapiens with 2 samples.

How the data were processed

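Total RNA of KYSE-170 cells, a human oesophageal squamous carcinoma cell line, was measured after transfection with 1 of 2 oligoribonucleotides. Per the labels, 1 sample received an oligoribonucleotide called ncRNA and the other received miR-210, a microRNA known to be induced by hypoxia. Per the labels' protocols, aminoallyl-cRNA was made from 500 ng of total RNA, labelled with Cy5 and hybridised to a 1-colour oligonucleotide array (Toray). There was 1 array per transfection, so no comparison has a replicate. Groups were taken from the sample titles. The labels do not say what the ncRNA sequence is, and it serves here only as the comparison arm.

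The deposited table holds intensity values on a linear scale for 24267 probes on each array. The unit was read from the values: they are whole numbers between -8 and 65496, and the highest lie just under the limit of a 16-bit scanner. The scanner, the background correction and any normalization by the authors are not given in the sources used here. Values under 0 occur, which requires that a background had been subtracted before deposit. The ncRNA column had a median of 39 and the miR-210 column a median of 36. Values above 65000, treated as saturated, numbered 5 on the ncRNA array and 1 on the miR-210 array. Detection calls and control spots were not used here.

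Values were taken to the log2 scale for the 24177 probes above 0 on both arrays, which left out 90 probes. The design set before the data were examined compared the column medians over probes with a value in both columns. It kept the deposited scale if they differed by no more than 0.1 on the log2 scale, and otherwise asked for quantile normalization. Over all probes the medians differed by -0.12, and on this reading of the plan the arrays were quantile normalized. Over the probes above 0, which the level filter uses, the difference was -0.08, under the limit. On that reading the plan keeps the deposited scale, so the unnormalized values were carried as an alternative. A probe was kept if its mean log2 level over both arrays reached the median of all probes, an intensity of 37.5 after normalization. This filter kept 12089 probes.

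Gene names came from the platform annotation. Of the 24267 probes, 13395 had exactly 1 symbol, none had several, and 10872 are unnamed here. Of the 12474 symbols, 2285 were updated to a current symbol through an unambiguous synonym in the RefSeq gene table of GRCh38.p14, and 113 of the resulting names matched no current symbol and were left as they were. No coordinates are given, because no genome build is named for the array. A gene with several kept probes took the probe with the highest mean level. After these steps 6681 genes remained, 251 of them with 2 or more kept probes.

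The log2 ratio is always miR-210 minus ncRNA. With 1 array per group no p-value was computed, and genes were named by size. A total of 27 gene lists were fixed before the data were examined. For lists with at least 3 kept members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from the kept genes and matched on mean level in 20 bins. A list is described as standing apart when its median lay outside the central 95% of the random medians. This describes these 2 arrays only, because genes of a pathway vary together and random genes do not. The procedure was tested on simulated data built on the 6681 real gene levels, with 100 simulated lists per setting. With no shift, 6 of 100 lists of 11 genes, 4 of 100 lists of 16 genes and 1 of 100 lists of 32 genes fell outside. With a shift of 0.4 on the log2 scale, 63, 76 and 98 of 100 lists were found at those sizes. The simulated lists and the random lists were drawn from the same real ratios, centred and shuffled among genes of like level. The low counts with no shift therefore follow from the construction. Lists whose genes vary together were not simulated. Quantile normalization of 2 simulated arrays of 24177 probes gave a median log2 ratio of -1.01 for probes changed by -1 and 1.93 for probes changed by 2. Single probes scattered around these medians with SDs of 0.42 and 0.38. Only 100 probes were changed by each amount, all of them well above the level filter. Changes at dim probes and a shift of many genes at once were therefore not covered.

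The only error available comes from probes of the same gene on the same pair of arrays. Over the 251 genes with 2 or more kept probes, the log2 ratio of a single probe had a SD of 0.44 around its gene, comparing the 2 brightest probes. The log2 ratios of the 2 probes correlated across these genes with a Spearman rho of only 0.29. For comparison, the log2 ratios of all genes kept had a SD of 0.54. The SD of 0.44, called the spread between probes below, covers probe noise, isoforms and errors of annotation. It leaves out differences between cultures, RNA preparations and arrays. The number of arrays limits the precision.

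The named genes followed a rule fixed before the data were examined. They are every kept member of the core list of reported miR-210 targets, the 8 genes with the highest and the 8 with the lowest log2 ratio after leaving out placeholder symbols and genes whose kept probes disagreed in sign, and up to 4 members per list with the largest absolute ratio. The target lists were written from general knowledge of reported targets. The study is known for following up FGFRL1, which may have been chosen on these arrays. Alternatives were the unnormalized values, median centring, loess on level with a span of 0.3, no level filter, a level filter at the 75th percentile, an offset of 10 (the 10th percentile of the deposited values) before log2, the mean over a gene's probes, random lists not matched on level, a 1.5-fold threshold and the core list without FGFRL1. A planned comparison of genes with and without miR-210 seed sites was not run, because 3' UTR sequences were not used here. A family of genes that stood apart on the lower side is not reported here. Computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots used matplotlib 3.10.9.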

Results

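The series asked which transcripts of KYSE-170 cells differ after transfection with miR-210, against cells transfected with the oligoribonucleotide called ncRNA. Each arm had 1 array, so every value below is a single measurement. The ncRNA array had a median intensity of 39, with a 25th percentile of 17 and a 75th percentile of 162, and the miR-210 array had a median of 36, with corresponding values of 17 and 150. Intensities of the 2 arrays correlated across all 24267 probes with a Spearman rho of 0.92, where probes are not independent replicates. Differences are given as the log2 ratio of miR-210 over ncRNA after quantile normalization, and folds are taken from it. A log2 ratio of a single probe had a SD of 0.44 around its gene, and no error between cultures can be given.

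FGFRL1, an FGF receptor family member without a kinase domain and the gene that the study is known for, had the lowest log2 ratio of all 6681 genes kept. Its intensity was 277 on the ncRNA array and 21 on the miR-210 array, a log2 ratio of -3.64 or 12.5-fold lower with miR-210, and 8.8-fold lower when an offset of 10 was added to every value. RNF11, a RING finger protein, was 6.77-fold lower, with intensities of 949 and 129. STMN1, which encodes the microtubule-destabilising protein stathmin, was 5.95-fold lower (1003 and 153). DDOST, a subunit of the oligosaccharyltransferase, was 5.16-fold lower (2238 and 391). At the other end, IL1RL1, the receptor for interleukin 33, was 12.2-fold higher with miR-210, from 20 to 231, and 8.45-fold higher with the offset, and SNRPC, a component of the U1 small nuclear ribonucleoprotein, was 6.06-fold higher, from 654 to 3541.

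Among 6681 genes, 202 were at least 2-fold higher and 212 at least 2-fold lower on the miR-210 array, together 6.2% of the genes. Without between-array normalization the same counts were 140 and 318, and the share of higher genes among them was 30.6% in place of 48.8%; that scale places the median gene at a log2 ratio of -0.12 in place of 0.01. A difference of at least 4-fold was seen for 7 genes in the higher direction and 15 in the lower. The remaining genes of the 8 lowest were PLAC8 (121 and 17), the matricellular glycoprotein gene THBS1 (206 and 37), the AP2-associated kinase AAK1 (221 and 43) and CARMIL1 (101 and 21), with log2 ratios of -2.77, -2.37, -2.25 and -2.18. The remaining genes of the 8 highest were the annexin ANXA10 (55 and 275), FAM135A (46 and 188), VKORC1L1 (257 and 998), the cytokine IL11 (38 and 148), the arginyltransferase ATE1 (49 and 183) and the guanylate-binding protein GBP6 (25 and 91), with log2 ratios of 2.44, 2.14, 2.09, 2.07, 2.01 and 1.96.

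The weaker side of these extreme ratios often lay near the bottom of the intensity range. FGFRL1 and PLAC8 on the miR-210 array, at 21 and 17, and IL1RL1 on the ncRNA array, at 20, were all under the median of their array. Such values are close to those of collagen genes of fibroblasts, where COL1A1 read 21 and 16 on the 2 arrays; COL1A1 was named after its values were seen. The true size of these ratios is therefore uncertain, and their direction rests on 1 array per arm. In all, 44 of the 212 genes at least 2-fold lower had a miR-210 value under the array median, and 46 of the 202 at least 2-fold higher had an ncRNA value under it. In all, 17 genes at least 2-fold apart had a second kept probe. The second probe had the same sign in 14 and was itself 2-fold apart in the same direction in 3. Each of the 8 lowest and 8 highest genes named above had only 1 kept probe, so no second probe checks their ratios.

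**Figure D1:**
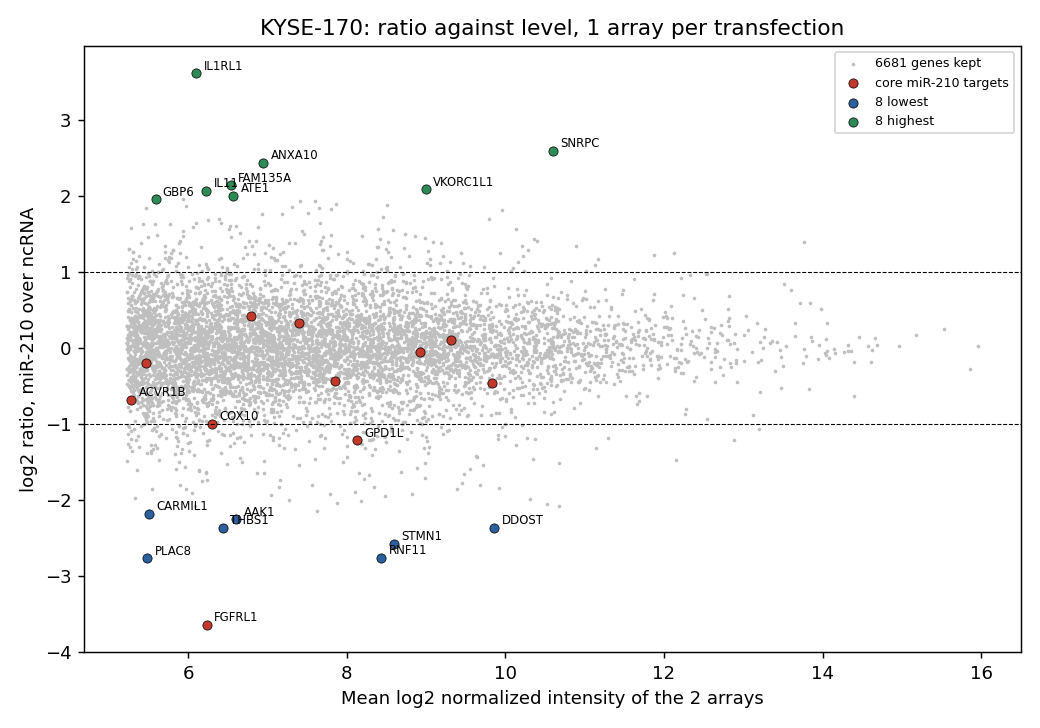
Log2 ratio of miR-210 over ncRNA (vertical axis) against the mean log2 normalized intensity of the 2 arrays (horizontal axis), 1 point per gene for 6681 genes; dashed lines mark 2-fold. FGFRL1, drawn with the core miR-210 targets, lies at -3.64 and is the lowest gene, while IL1RL1 lies at 3.61 and is the highest.

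The core list held 15 genes reported as miR-210 targets, of which 12 were named on the array and 11 passed the level filter. The median log2 ratio was -0.43, at percentile 0.56 of random lists matched on level, with 8 members under 0 and 3 above. After FGFRL1 the lowest were GPD1L, a glycerol-3-phosphate dehydrogenase-like protein, at -1.21 (449 and 177), COX10, a cytochrome c oxidase assembly factor, at -0.995 (116 and 54), and ACVR1B, an activin receptor, at -0.68 (51 and 30). P4HB, which encodes protein disulphide isomerase, stood at -0.47 and ISCU, the iron-sulfur cluster scaffold, at -0.43. RAD52 and EFNA3 were nearer 0, at -0.19 and -0.06. The ratios of E2F3, PTPN1 and CASP8AP2 were 0.11, 0.34 and 0.42. Only FGFRL1, GPD1L, COX10, ACVR1B and P4HB differed from 0 by more than 0.44, the SD of a probe around its gene. P4HB did so only at its brighter probe, with its other kept probe at -0.40. Ratios of this size were common among all genes kept: their SD was 0.54, and ISCU ranked 1136 from the lowest.

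FGFRL1 may have been chosen by the study on these samples, so its place in the list is not independent evidence. Without it the median of the other 10 members was -0.31, at percentile 3.19, which is inside the central 95% of random lists. With the level filter at the 75th percentile, 6 members remained with a median of -0.24 at percentile 10.8, and FGFRL1 itself was removed.

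**Figure D2:**
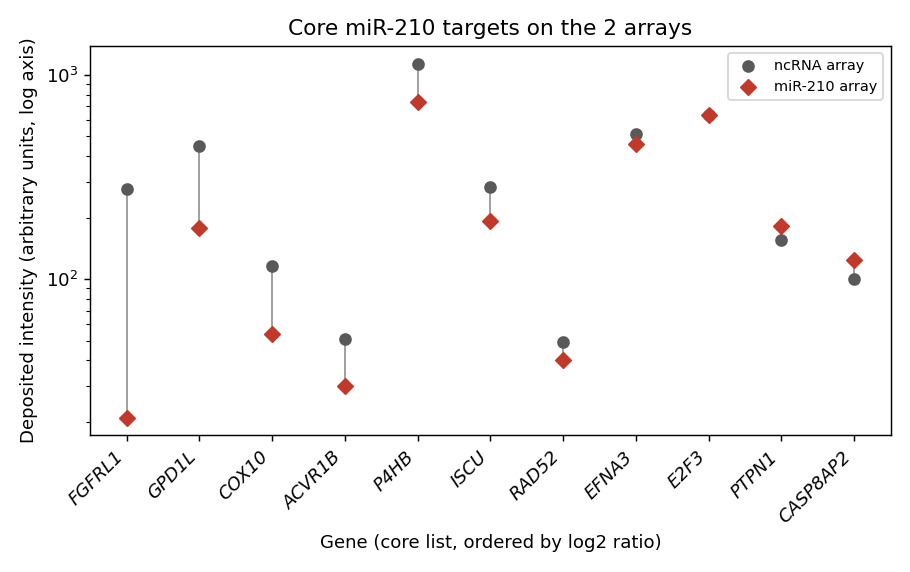
Deposited intensity (vertical log axis, arbitrary units) of the 11 kept core miR-210 targets on the ncRNA array (circles) and the miR-210 array (diamonds), ordered by log2 ratio; grey lines join the 2 values of a gene. FGFRL1 goes from 277 to 21 and GPD1L from 449 to 177, while E2F3 reads 636 and 637.

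The wider list of 41 less firmly established targets gave 24 kept genes, 12 above 0 and 12 under it. Its median was -0.12, at percentile 11.7, and did not stand apart. Over all settings the median ranged from -0.32 without between-array normalization, at percentile 3.08, to -0.008 with no level filter, at percentile 41.0. Its 4 most distant members were all lower with miR-210: STMN1 at -2.57, the inositol phosphatase INPP5A at -2.08 (146 and 32), the homeobox gene HOXA9 at -1.37 (883 and 311) and MID1IP1 at -0.97 (254 and 121).

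Genes of sterol synthesis were higher on the miR-210 array. Of 15 kept members, 12 were above 0, and the median of 0.35 lay at percentile 99.2 of random lists. MSMO1, a sterol methyl oxidase, was 2.73-fold higher (322 and 801), IDI1, the isopentenyl diphosphate isomerase, was 2.5-fold higher (279 and 645) and NSDHL, a sterol dehydrogenase, was 2.13-fold higher (50 and 99). MVD, the mevalonate diphosphate decarboxylase, went the other way at 1.84-fold lower (148 and 74). Over all settings run for this list the percentile stayed between 99.1 and 99.9.

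The epithelial junction list was also higher, with 14 of 17 kept members above 0 and a median of 0.35 at percentile 99.3. Besides junction genes it holds the keratins KRT8, KRT18 and KRT19 and the transcription factors GRHL1, GRHL2, OVOL1 and OVOL2. The tight junction gene OCLN stood at 0.96 (241 and 431), the transcription factor GRHL1 at 0.95 (31 and 56) and the simple-epithelium keratin KRT18 at 0.77 (10285 and 14550). The other kept probe of OCLN stood at 0.53. The tight junction gene CLDN1 was 2.4-fold lower (474 and 182), the largest difference in the list. The percentile was between 98.7 and 99.7 over all settings run. The mesenchymal list, with 9 kept members, had a median of -0.02 at percentile 42.8, and with no level filter 19 members gave -0.28 at percentile 3.11. In that list THBS1 was 5.16-fold lower, the transcription factor SNAI2 was 2.32-fold lower (501 and 201), FN1 stood at 0.75 (41 and 64) and CCN1 at -0.33.

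Basal squamous cell genes had a median of 0.30 at percentile 98.2, with 14 of 16 kept members above 0. ITGA6, an integrin of the hemidesmosome, was 3.71-fold higher (125 and 428), and KRT5 and PKP1 stood at 0.90 and 0.80. SOX2 was 1.94-fold lower (90 and 43). This list no longer stood apart in 5 of its 8 alternatives, where its percentile went down to 90.4. Squamous differentiation genes did not stand apart, with a median of 0.05 at percentile 59.6 over 13 members. CSTA was 2.35-fold lower (569 and 226) and KRT4 1.84-fold lower (97 and 49), while KRT17 was 2.02-fold higher (1541 and 2736) and KRT16 1.48-fold higher.

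Genes of the unfolded protein and amino acid response had a median of 0.24 at percentile 97.6, with 12 of 21 members above 0. ATF3, a stress-induced transcription factor, was 2.66-fold higher (69 and 170), VLDLR was 2.64-fold higher (38 and 93), the endoplasmic reticulum co-chaperone DNAJB9 was 2.26-fold higher (229 and 480) and the cystine transporter SLC7A11 was 1.94-fold higher (185 and 331). The median turned to -0.10 with the level filter at the 75th percentile, where 16 members were left, and the list was inside the central 95% with an offset added before log2 (percentile 97.4) and among random lists not matched on level (96.8). Genes of the small RNA pathway had a median of -0.43 at percentile 1.47 over 9 members, 7 of them under 0. TNRC6C, a partner of Argonaute proteins, was 2.19-fold lower (190 and 80), and GEMIN4, PRKRA and DICER1 stood at -0.92, -0.86 and -0.50. Without a level filter 15 members gave a median of -0.08 at percentile 32.8, with the filter at the 75th percentile 3 members gave -0.30 at percentile 14.6, and the mean over the probes of TNRC6C was -0.67.

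The cell cycle lists did not stand apart. The list of G1/S and DNA replication genes had a median of 0.00 at percentile 51.0 over 30 members, split 15 and 15 around 0, with E2F2 at -1.14, CDC45 at -0.998, UHRF1 at 0.55 and MCM10 at 0.55. The list of G2/M and mitosis genes had a median of 0.00 at percentile 49.8 over 32 members, with PLK4 at 0.98, BIRC5 at -0.97, HMMR at 0.97 and NEK2 at 0.78. In the p53 target list 13 of 18 members were above 0, with a median of 0.06 at percentile 68.7; BBC3, a pro-apoptotic BCL2 family gene, was 1.86-fold higher (152 and 260) and the cyclin-dependent kinase inhibitor CDKN1A was 1.73-fold higher (504 and 802), while XPC stood at 0.54 and BTG2 at -0.51. The apoptosis list had a median of 0.06 at percentile 66.4 over 18 members, with DIABLO at -0.98, BID at -0.80, MCL1 at -0.75 and BIK at 0.58.

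Genes tied to FGF signalling, the pathway of FGFRL1, did not stand apart either. The FGF and ERK response list had a median of 0.18 at percentile 90.8 over 17 members, with SPRED2 2.15-fold lower (454 and 194), FOS 2.06-fold higher (37 and 71), VGF at -0.90 and IER2 at 0.63. FGF receptors and ligands had a median of 0.12 at percentile 65.5 over 10 members, with FGF2 at -0.92, FGFR2 at -0.73, FRS3 at 0.71 and FGFBP1 at -0.55.

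The hypoxia response list had a median of 0.17 at percentile 89.6 over 20 members. ANGPTL4, a secreted regulator of lipoprotein lipase, was 3.62-fold higher (87 and 289), and P4HA2 stood at 0.79, while NDRG1 was 2.17-fold lower (112 and 48) and the prolyl hydroxylase EGLN3 2.0-fold lower (64 and 30). Glycolysis genes had a median of -0.03 at percentile 34.6 over 13 members, and respiratory chain and iron-sulfur assembly genes a median of -0.01 at percentile 35.99 over 45 members. No member of either list reached 2-fold. ENO2, HK1, PGAM1 and ALDOC stood at 0.61, 0.54, 0.44 and 0.43, and UQCRFS1, NFS1, NDUFS7 and COX5B at 0.88, -0.82, 0.74 and -0.67.

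Of the lists on innate and stress responses, the interferon list had a median of -0.10 at percentile 20.2 over 19 members, with IFI44 at -1.12, OASL at -0.95, OAS1 at -0.73 and STAT2 at -0.57. The list of NF-kB targets had a median of 0.02 at percentile 52.98 over 17 members; the chemokine genes CXCL3, CXCL1 and CXCL8 were 2.13-fold, 2.13-fold and 1.99-fold lower, and PTGS2 was 1.94-fold higher (174 and 312). The heat shock list, at 0.27 and percentile 96.5 over 8 members, lay just inside the central 95%, with HSPH1 at 0.64, DNAJA1 at 0.52, HSP90AB1 at 0.39 and HSPB1 at 0.39. The other kept probe of HSP90AB1 stood at 0.19. Histone genes had a median of -0.24 at percentile 4.66 over 11 members, with H1-2 at -0.86, H2BC5 at -0.79, H2AC6 at -0.56 and H3C4 at 0.57, the last of which was 0.06 as a mean over its probes. Cytosolic ribosomal protein genes had a median of -0.04 at percentile 22.3 over 17 members; RPL22 was 3.8-fold lower (928 and 224), RPL5 stood at 0.59, and RPS2 and RPS3 both at -0.18.

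Markers of other cell types were mostly under the level filter and did not stand apart as lists. The filter kept 6 of 15 fibroblast and smooth muscle markers on the array, with a median of 0.06 at percentile 56.2, among them COL5A1 at 0.79, COL6A3 at 0.41, DES at -0.24 and DCN at 0.10. Of 9 endothelial markers 4 were kept, with a median of -0.07 at percentile 39.7, and KDR, ESAM, VWF and ENG stood at -0.77, 0.65, -0.18 and 0.04. The single leukocyte marker kept of 14 was CD79A, at 0.02. The 7 kept markers of liver, nerve and germ cells had a median of -0.09 at percentile 30.6, with TUBB3, a neuronal tubulin also expressed by tumour lines, 2.14-fold higher (221 and 437), and SYP, GFAP and MBP at -0.57, -0.42 and -0.40. In total 6 of the 26 lists with a percentile stood apart, 4 higher and 2 lower, where independent genes would give 1.3. Genes of a pathway vary together, so an excess over 1.3 is not by itself evidence of an effect of miR-210. Of these, sterol synthesis and epithelial junctions stood apart under every alternative run, and the core targets, basal squamous cells, unfolded protein and small RNA lists each lost this in 2 or more. The mean of a list opposed its median in sign for G1/S (-0.03), G2/M (0.08), apoptosis (-0.003), FGF receptors (-0.05), glycolysis (0.10), the respiratory chain (0.01), NF-kB targets (-0.09) and squamous differentiation (-0.09), all lists inside the central 95%. Without between-array normalization the medians of the G1/S, p53, apoptosis, NF-kB, squamous differentiation and fibroblast lists turned under 0 with the shift of all genes, at percentiles between 52.1 and 67.2, and the 6 lists that stood apart kept their sign.

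**Figure D3:**
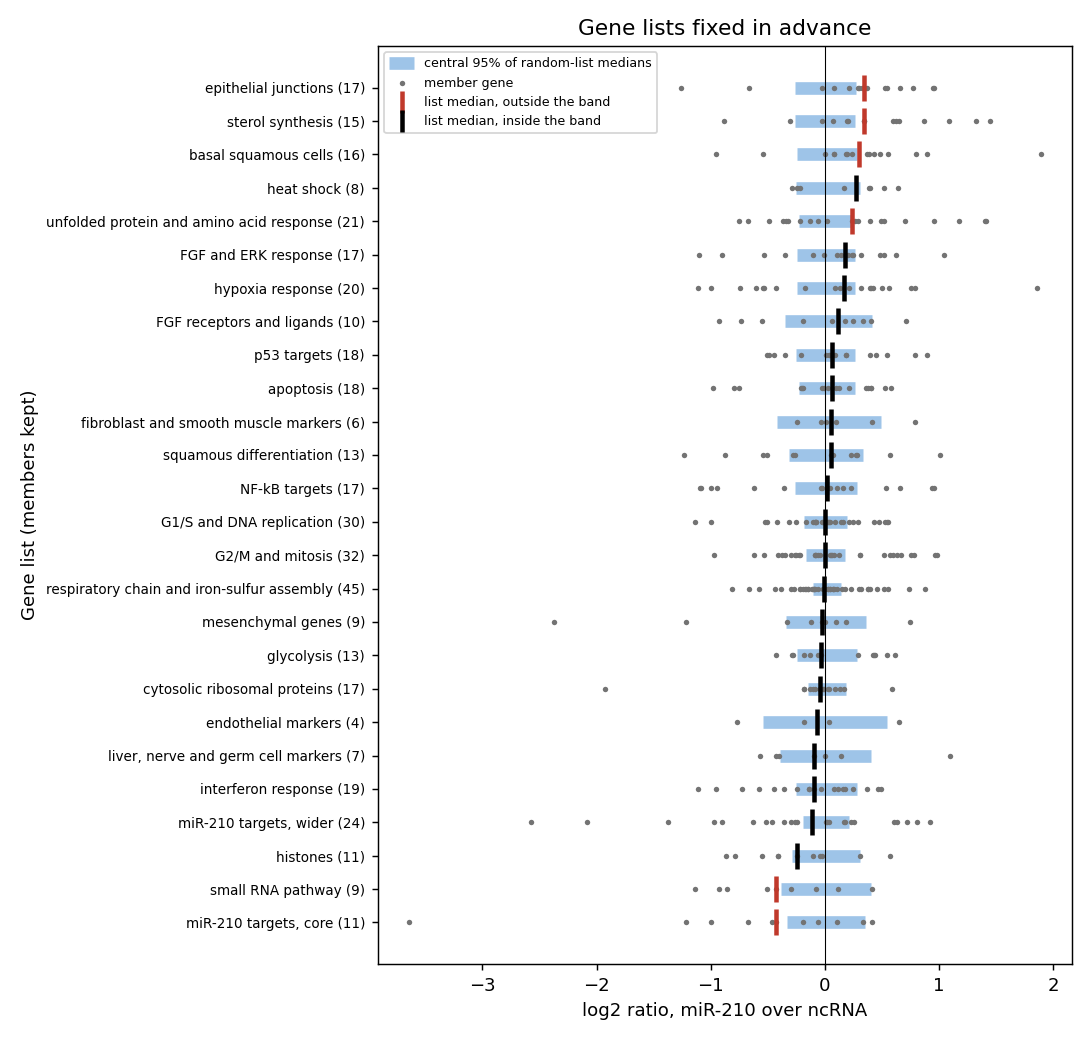
Log2 ratio of miR-210 over ncRNA (horizontal axis) for the kept members (grey points) of 26 gene lists (rows, with the number kept), with the list median (vertical bar, red if outside the band) and the central 95% of medians of 10000 random lists matched on level (blue band). The core targets and the small RNA pathway lie under their bands at -0.43, and sterol synthesis, epithelial junctions, basal squamous cells and the unfolded protein and amino acid response lie above theirs.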

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

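The settings with loess on level and without FGFRL1 were planned before the data were examined; the count in the lowest 5% of genes and the comparison with fibroblast markers were chosen after the result was seen, as was the reading of the planned settings as tests of an explanation. Of the probes with no gene name in the annotation used here, 5132 passed the level filter. Of these, 123 were at least 2-fold higher and 142 at least 2-fold lower on the miR-210 array. Together they made up a smaller share of the unnamed probes than the 6.2% found among named genes. They were picked out because they carry signal that no gene comparison uses, not because they were frequent. The lowest was probe H300009397, with intensities of 4846 on the ncRNA array and 593 on the miR-210 array, or 7.4-fold lower. The highest was probe opHsV0400009031, with 93 and 701, or 8.25-fold higher.

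The core list of reported miR-210 targets lay low on the miR-210 array, while the wider list, with 12 members above 0 and 12 under it, did not stand apart. The core list was at percentile 0.63 after loess on level. The random lists were already matched on level, so this value adds little about a trend with level. Without FGFRL1 the percentile was 3.19, so a place of the list that rests on FGFRL1 remains open. Of the 35 kept members of both target lists, 8 were in the lowest 5% of all genes, where the central 95% of random lists matched on level reached at most 5; without FGFRL1 it was 7 of 34, against at most 5. The wider list had 5 of 24, where random lists averaged 1.2 and their central 95% reached at most 4. The core list without FGFRL1 had 2 of 10, where random lists averaged 0.55 and their central 95% reached at most 2. Repression of reported targets by miR-210 stays a hypothesis, since with 1 array each a difference between cultures or arrays was not separable from the transfection.

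Sterol synthesis genes were higher on the miR-210 array. The percentile was 99.2 after loess on level and at least 98.98 when each member was left out in turn. Neither value could readily have come out otherwise. The random lists were already matched on level, and a median moves little when 1 member is dropped. A response to miR-210 is one hypothesis, and a difference in culture conditions such as cell density or lipid supply, which could shift the same genes, is another. With 1 array per arm nothing in these data decides between them.

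The epithelial junction list, which also holds keratins and transcription factors, was higher on the miR-210 array. The percentile was 99.14 after loess on level and at least 98.77 when each member was left out in turn. As for sterol synthesis, neither value could readily have come out otherwise. The fibroblast and smooth muscle list lay at percentile 56.22. COL1A1, COL1A2 and COL3A1 read 21, 10 and 20 on the ncRNA array, under the level threshold of 37.5. Other markers of that list lay above it, among them DCN (183 and 181) and COL5A1 (95 and 152). The samples are of a cell line, with no fibroblasts to lose, so this comparison could not have come out otherwise and decides nothing. A state difference between the cultures, from miR-210 or from density, stays open and untested.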

How the results depend on the processing

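Against the values reported, 208 alternative values for counts, lists and FGFRL1 kept their side of the central 95% or, for counts, stayed within 1.5 times (140 higher and 318 lower without further normalization among them) or, for FGFRL1, moved by less than the spread between probes, and 7 counts or FGFRL1 values moved further. For the lists that stood apart, 11 values no longer did and 1 turned sign, and 1 list came to stand apart. Medians of lists inside the central 95% turned sign 19 times, in 12 lists, and stayed inside it; for the other named genes 805 of the alternative values moved by less than the spread between probes and 4 by more, with no direction turned among genes at least 2-fold apart. The counts of genes at least 2-fold higher and lower were 878 and 823 with no level filter (12405 genes), 95 and 98 with the filter at the 75th percentile (3467 genes), and 794 and 726 at a 1.5-fold threshold. The share of genes at least 2-fold apart was 13.7% with no level filter against 6.2% as reported, so dim probes add more than their number. FGFRL1 stood at -3.14 with the offset and had no value with the filter at the 75th percentile, which also left 3 lists with under 3 members without a value. The core targets had a median of -0.24 with the filter at the 75th percentile and -0.31 without FGFRL1. The basal squamous list had medians of 0.10 without further normalization, 0.23 after loess, 0.24 with no level filter, 0.21 with the filter at the 75th percentile and 0.23 with the offset. The unfolded protein and amino acid list turned to -0.10 with the filter at the 75th percentile, stood at 0.23 with the offset, and kept its 0.24 at percentile 96.8 among random lists not matched on level. The small RNA list was at -0.076 with no level filter and -0.30 with the filter at the 75th percentile, where 3 members were left. The heat shock list came to stand apart at 0.39 with no level filter. The cause was not tested for these lists. The seed-site comparison was not run, since 3' UTR sequences were not used here, and no replicate could be left out. No paired analysis was possible because each arm had a single array. Signal near background limits all genes whose lower value is under the array median.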

Other observations

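Gene families defined by a shared symbol stem, a grouping chosen after the data were seen, were scanned as well. Of 63 families with at least 10 kept genes, 5 stood apart from random lists, where independent genes would give 3.15. Of the 5, 4 are described here. Keratins had a median log2 ratio of 0.35 at percentile 99.5, with 12 of 16 above 0, from KRT4 at -0.88 to KRT17 at 1.01. Of the 16, 11 are also members of the lists fixed in advance, so most of the family repeats those lists. The 5 keratins in no fixed list had a median of 0.36, with 3 above 0. Proteasome beta subunits had a median of 0.30 at percentile 98.3, with 9 of 10 above 0; PSMB1 was highest at 0.71 and PSMB9, a subunit of the immunoproteasome, lowest at -0.32. General transcription factor genes with the GTF stem had a median of 0.30 at percentile 98.7, with 10 above 0 and 7 under it, among them GTF2B at 0.86 and GTF3C1 at -0.68.

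Vacuolar sorting genes of the VPS stem had a median of -0.24 at percentile 2.34, with 8 above 0 and 13 under it and 3 of 21 at least 2-fold lower, among them VPS45 at -1.89. The excess of families over the number that independent genes would give is small, and no family was tested in further arrays.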
